A study of Mus musculus with 12 samples.

How the data were processed

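RNA was measured in 12 pituitary glands of adult males, labelled as F1 of C57BL/6J and 129S1/SvlmJ, 6 from zygotes injected with vehicle and 6 from zygotes injected with the let-7f-5p mimic. The labels do not say which animals shared a litter or a recipient dam, so that litter could not be modelled. The libraries were stranded and made from rRNA-depleted total RNA, per the labels' protocols.

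Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, quantified with kallisto 0.50.1 against GRCm39 and normalised with DESeq2 1.48.2, with quality reports from FastQC 0.12.1 and MultiQC 1.28. The deposited values are a signal per gene in the form of normalised read counts, in 1 table with 12 columns, all of which were used. In every column each value was a whole multiple of 1 step, the inverse of that library's size factor (0.817 to 1.17). Dividing by the step gave whole numbers for 100% of the values, within 0.001 of a whole number. These are called recovered reads. kallisto's estimated counts need not be whole, and no header or label records how whole numbers arose. A row without a gene name held 0.0359% to 0.0567% of a library's reads and was left out. Summed over named genes, recovered reads ranged from 26378308 to 37061136 per library. Each library had between 10 and 56 genes at 0, so the table had been filtered for low genes before deposit. The closest pair of libraries differed 19.3 times more than counting error alone (chi-square per degree of freedom), so no library was a copy of another. Estimated counts of overlapping or near-identical genes depend on how kallisto divided shared reads.

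The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(value + 1) of the deposited normalised counts. Genes were kept with a value of at least 10 in at least 6 of the 12 libraries (18390 of 18497). There were no covariates, and the threshold was a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. On the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) were run as alternatives. DESeq2 gave no adjusted p for 2866 genes.

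Gene lists were fixed before the data were examined: 32 lists, of which 31 had at least 5 measured genes. The list of sex-linked genes was used only for the check of the male label. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists, with camera at an estimated correlation and fry beside it. Some lists share genes, such as Gata2 in the gonadotroph and thyrotroph lists.

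Matches to the let-7 seed (CTACCTC, and CTACCTCA for the 8mer) were searched in the 3' UTR of 1 transcript per gene of GENCODE M21. That annotation is on GRCm38 and not on the authors' build, and it was used by gene symbol alone: 17107 of 18497 symbols matched (92.5%), 15361 of them with a 3' UTR. Single values per library were compared by an exact two-sided permutation test over all 924 assignments.

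The genes named were chosen by a rule written before the data were examined. It takes up to 10 genes per direction with the largest change among those past the threshold, filled up to 10 with those of smallest p and skipping unnamed gene models (0 were skipped in either direction). It adds the 7 hormone genes, the 2 to 4 members of smallest p of each list, 10 genes tied to let-7 where measured, and Xist and Ddx3y. Not every gene that the rule chose is named in the text.

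The gene tests were tested on simulated counts with the means and library sizes of this comparison, 18390 genes and 200 changed genes. The changed genes were drawn only from those with a mean of at least 50, so recovery of lower genes was not tested. At a simulated fold of 1.5, 2, 3 and 4, limma recovered 62%, 90%, 96% and 100% of 50 genes each, and 6.45% of its calls were false. For edgeR the false share was 6.01% and for DESeq2 19.7%. In simulated lists of independent genes, camera recovered the list that had been shifted by 0.3 and called 0 of 30 lists that had not.

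Alternatives were another pseudocount (0.5, 5), no filter, a minimum of 50, TMM rescaling, quantile normalisation, library weights, robust variance, the replicate number as a block, the posterior lobe markers as a covariate, and leaving out each library in turn. For the seed matches they were 8mer sites, genes with 2 or more sites, and the matched background.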

Results

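Pituitary glands of adult male mice were profiled by RNA sequencing of total RNA from which ribosomal RNA had been removed. The mice had been injected as zygotes with the let-7f-5p microRNA, given as a chemically stabilised mimic in a concentration named stress-relevant by the labels, or with the water used as its vehicle. The vehicle group and the mimic group held 6 glands each, 1 library per gland. The deposited table listed normalised read counts for 18497 named genes. The reads recovered from it, summed over named genes, ranged from 26378308 to 37061136 per library. The comparison of the groups asks whether a rise of let-7f in the zygote leaves a trace in the transcriptome of the adult gland that makes growth hormone, prolactin, thyrotropin, the gonadotropins and corticotropin.

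No gene passed the threshold. Limma-trend on log2(normalised count + 1), with Benjamini-Hochberg adjustment over 18390 genes, called 0 genes higher and 0 lower in the mimic group (n = 6 against 6). The smallest adjusted p was 0.822. At an unadjusted p under 0.05 there were 879 genes, 421 higher and 458 lower, against 920 that chance gives. On the recovered reads, edgeR's quasi-likelihood test called 0 genes, with 868 at an unadjusted p under 0.05, and DESeq2 called 10 genes, with 927. The groups did not overlap for 22 genes, and random grouping gives about 39.8 such genes, or 0.216% of those tested. The 95% confidence interval of the fold change lay within a 2-fold change in either direction for 93.6% of the tested genes. For the 15276 genes with a mean of at least 50 the share was 97.4%. These unadjusted intervals hold for single genes and take the glands as independent, although litter could not be modelled. Under that assumption, changes above 2-fold in the RNA of the gland lay outside the interval for most genes. The median standard error was 0.113 on the log2 scale.

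The genes of smallest p are given as values that did not pass. Among those lower in the mimic group, the sodium-calcium exchanger gene Slc8a3 had 241 ± 31.1 normalised counts in vehicle glands and 155 ± 18.4 in mimic glands (mean ± SD, n = 6 each). Its log2 fold change was -0.63 (SE 0.11, limma adjusted p 0.822), and all 6 mimic libraries lay below the vehicle mean. The ubiquitin-like modifier activating enzyme gene Uba7 had -0.47 (SE 0.09, limma adjusted p 0.822) and Shisa5 had -0.37 (SE 0.07, limma adjusted p 0.844) on the same scale. The other 7 were Taf6l, Dnajc4, Aatk, Ptprm, Xkr4, Asb4 and Slc2a1, with log2 fold changes from -0.54 to -0.21. Among those higher, the receptor tyrosine kinase gene Kit had 346 ± 110 normalised counts in vehicle glands and 666 ± 116 in mimic glands (mean ± SD, n = 6 each). Its log2 fold change was 0.99 (SE 0.20, limma adjusted p 0.844), with all 6 mimic libraries above the vehicle mean. The other 9 were Nudt5, Ddx11, Prp2rt, Sphkap, Mthfd1, Zfp609, Mtres1, Neto2 and the proliferation marker Mki67. Their log2 fold changes lay between 0.24 and 0.49, apart from Prp2rt at 2.90 (SE 0.69; 3.2825 with a pseudocount of 0.5 and 1.8957 with 5), a transcript at 0 in vehicle 1 and vehicle 4 and at 42.1 normalised counts at most. The limma adjusted p of these 16 genes was 0.976.

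The 10 genes that DESeq2 called were Slc8a3, Uba7, Shisa5, Taf6l, Xkr4, Aatk, Dnajc4 and Tlr7, which were lower in the mimic group, and Kit and Nudt5, which were higher. The DESeq2 adjusted p was 0.0014 for Slc8a3 and 0.0041 for Kit. Tlr7, which is named here only because of this call, rested on 3 libraries: it stood at 1740, 1730 and 1860 normalised counts in vehicle 1, 2 and 3 and between 15.7 and 52.3 in the other 9 libraries.

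**Figure D1:**
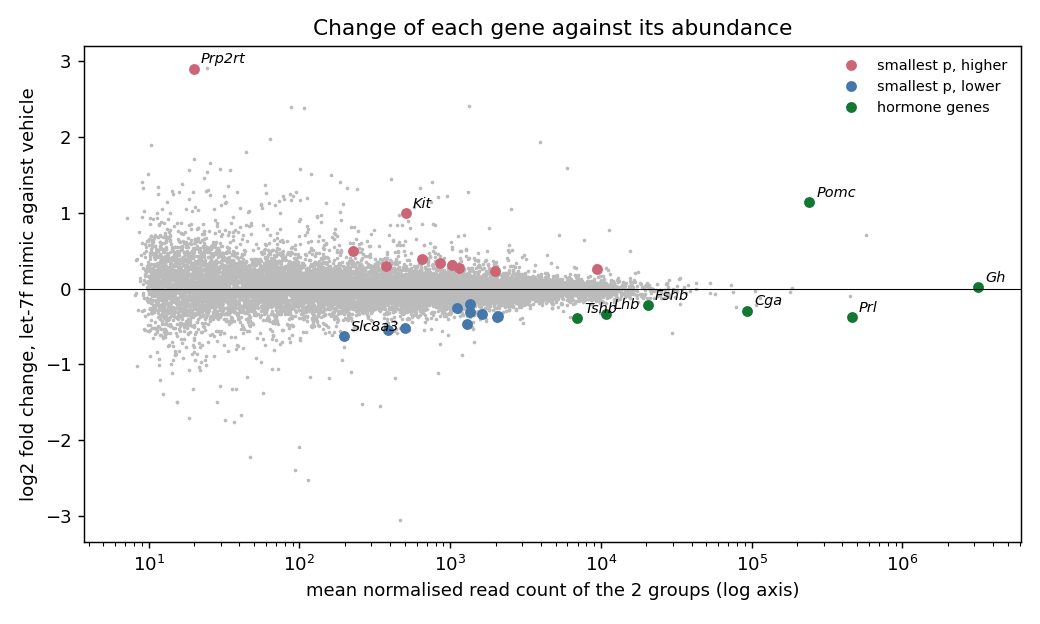
Log2 fold change of each tested gene, let-7f mimic against vehicle, against the mean of its normalised counts in the groups (log axis). Coloured points mark the 10 genes of smallest p in each direction and the 7 hormone genes; the largest change among the hormone genes is the 1.14 of Pomc.

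No difference was detected in the share of the libraries that the hormone genes took together. The 7 genes together held 12.9% ± 0.949 (SD, n = 6) of the summed normalised counts in mimic glands and 12.95% ± 1.87 in vehicle glands (exact two-sided permutation p 0.972, adjusted p 0.972 over 3 such tests). Growth hormone mRNA (Gh) alone made up 10.2% in vehicle glands, so the joint share says little about the other hormone genes. The log2 fold change of Gh was 0.02 (95% interval -0.25 to 0.29), a value whose sign changed when single libraries were left out. Pomc held 1.01% ± 0.513 in mimic and 0.56% ± 0.457 in vehicle glands (SD, n = 6 each, exact two-sided permutation p 0.139). Prolactin mRNA (Prl) had a log2 fold change of -0.38 that did not pass (SE 0.14, limma unadjusted p 0.0178, adjusted p 0.976), at 519075 ± 95973 normalised counts in vehicle and 399985 ± 76523 in mimic glands (SD, n = 6 each), with all 6 mimic libraries below the vehicle mean. The genes Tshb, Lhb, Cga and Fshb had log2 fold changes of -0.39, -0.34, -0.29 and -0.22 (SE 0.20, 0.18, 0.17 and 0.20), each with a limma adjusted p of 0.976. Without vehicle 4, which had the highest level of each of them, the values were -0.2594, -0.1572, -0.145 and -0.0791. Fshb was also at -0.3281 without vehicle 2 and at -0.1205 without mimic library 2. The corticotropin precursor gene Pomc had a log2 fold change of 1.14 that did not pass (SE 0.51, limma unadjusted p 0.0436, adjusted p 0.976), with 5 of 6 mimic libraries above the vehicle mean. It ranged from 45286 to 400805 normalised counts among vehicle glands and from 125740 to 606984 among mimic glands, and it followed the genes of the intermediate and posterior lobes from library to library. Adjusted over the list alone, 0 of the 7 genes passed, with a smallest limma adjusted p of 0.125 for Prl.

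**Figure D2:**
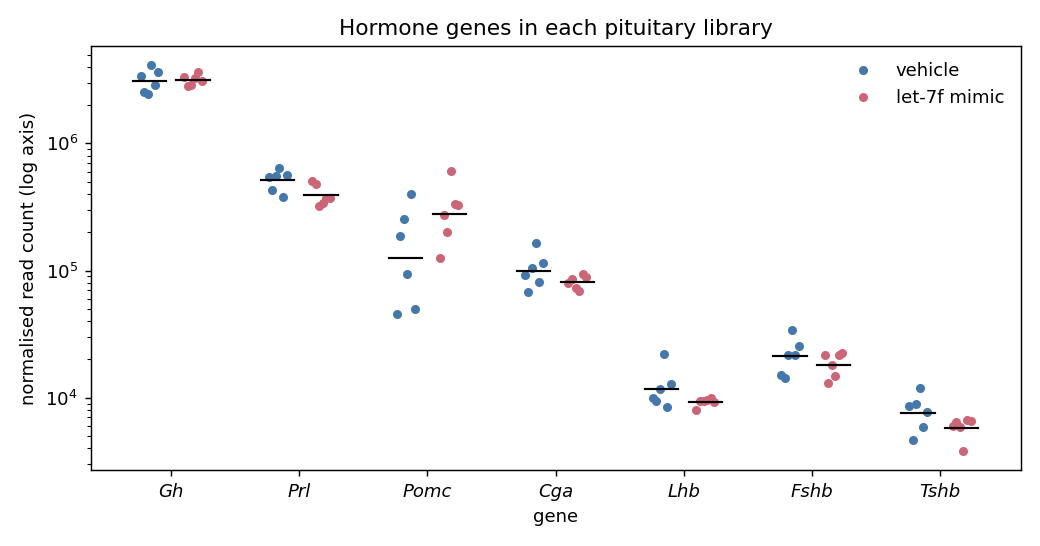
Normalised read count (log axis) of the 7 hormone genes in each of the 12 libraries, with the geometric mean of each group as a line. Gh lies between 2457503 and 4118190 in all libraries, and Pomc varies most, from 45286 to 606984.

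**Figure D3:**
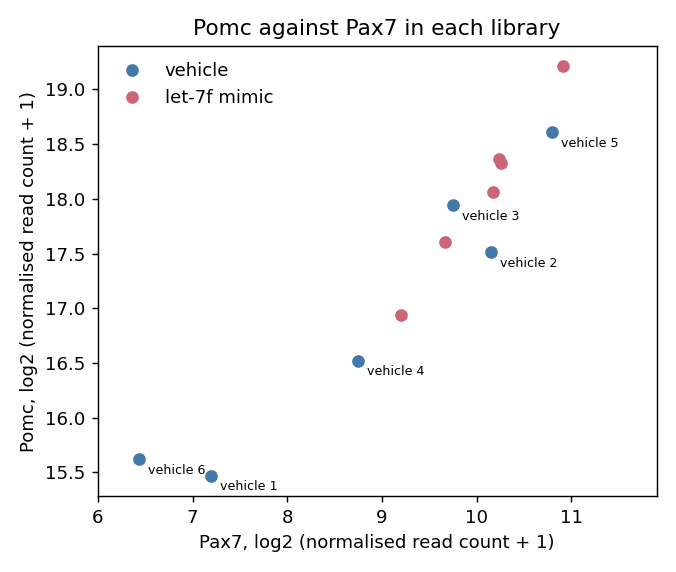
Log2 of the normalised count + 1 of Pomc against that of Pax7, a transcription factor gene of intermediate-lobe melanotrophs, with 1 point per library and the vehicle libraries named. Vehicle 1, 4 and 6 had the lowest values of both genes, with Pomc at 45286, 93810 and 50197 normalised counts.

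No difference was detected between predicted targets of the injected microRNA and other genes. Of the tested genes with an annotated 3' UTR, 1417 carried at least 1 match to the let-7 seed (7mer-m8 or 8mer) and 13900 carried none. Their mean log2 fold changes were 0.009 and 0.0047 (camera with the preset correlation, p 0.735). Against 1417 genes matched on 3' UTR length and GC content, the mean difference was 0.0021 (camera p 0.868, in the opposite direction to the means). Of the 53 let-7 targets fixed as a list from general knowledge, 49 were measured, 23 with a positive and 26 with a negative log2 fold change. Their median of -0.003 and mean of 0.032 differed in sign (camera adjusted p 0.614, direction up). The members of smallest p were Acvr1c at -0.70 and Arid3a at -0.21. The let-7 antagonist gene Lin28b was low, at 49.9 ± 37.4 normalised counts in vehicle and 88.1 ± 28.7 in mimic glands (SD, n = 6 each), with a log2 fold change of 1.10 (SE 0.43, limma unadjusted p 0.0224, adjusted p 0.976). It was lowest in vehicle 1, 4 and 6, the libraries lowest in Pomc and Pax7, and its log2 fold change was 0.6395 with the posterior lobe markers as a covariate. Hmga2, Igf2bp1, Igf2bp2 and Igf2bp3 had log2 fold changes of 0.14, 0.31, 0.15 and -0.09. Dicer1, Igf1r, Insr and Irs2 had log2 fold changes of -0.03, -0.02, 0.02 and -0.03, with intervals between -0.36 and 0.30. Trim71 was not among the genes in the table.

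Of 31 lists of genes fixed before the data were examined, 6 passed camera with its preset correlation of 0.01, and 0 passed camera with the correlation estimated from the data (smallest adjusted p 0.767) or the rotation test fry (smallest adjusted p 0.829, and 0.756 for changes in either direction). With camera, all 6 calls therefore depended on the preset setting, which treats the members of a list as nearly independent. At this setting, splits of the 12 samples other than the real one gave a median of 8 lists. The 48 cytosolic ribosomal protein genes had a median log2 fold change of -0.11, with 47 of 48 negative (preset camera adjusted p 6.12e-09), and an estimated correlation between genes of 0.844. Its level lay 0.30 and 0.27 (log2) above the mean of all libraries in vehicle 3 and vehicle 4. The median was -0.0596 without vehicle 3, -0.0633 without vehicle 4 and -0.1629 without vehicle 2, and the list passed each time. Rpl11, Rpl35 and Rpl32 were among its members of smallest p, at -0.18, -0.20 and -0.15. The 20 genes of the replication-dependent histone list had a median of -0.15 (preset camera adjusted p 0.000672), led by H2ac8, H3c3, H4c4 and H2bc6. The name of the list does not hold for its member H1f0, a replication-independent histone gene. The histone list did not pass without vehicle 3, where its median was -0.0783. The 35 nuclear genes of oxidative phosphorylation had a median of -0.06 (preset camera adjusted p 0.00807), led by Ndufa1, Cox5b, Atp5f1a and Atp5f1d. It did not pass without vehicle 3, vehicle 4 or mimic library 3, with medians of -0.0183, -0.0227 and -0.0274, and its median was -0.0993 without vehicle 2. The 14 gonadotroph genes had a median of -0.19 with 12 negative (preset camera adjusted p 0.000672), led by Gata2, Tgfbr3l, Inhbb and Lhb. Without vehicle 4 its median was -0.1199, and it passed. The 9 measured thyrotroph genes had a median of -0.20 with 7 negative (preset camera adjusted p 0.0126), with Gata2, Tshb and Tshr among the members of smallest p. It did not pass without mimic library 4, where its median was -0.1287. The 15 measured markers of the posterior lobe and its pituicytes had a median of 0.38 with 13 positive (preset camera adjusted p 0.00296), led by Mt3, Scn7a, Nkx2-1 and Cryab. It did not pass without vehicle 1, where its median was 0.2436, or without vehicle 6. The posterior lobe markers varied more among vehicle glands than between the groups, with a mean log2 level of 7.91 ± 1.32 in vehicle and 8.48 ± 0.188 in mimic glands (SD, n = 6 each, exact two-sided permutation p 0.305).

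The other 25 lists did not pass. The list of the 7 hormone genes had a preset camera adjusted p of 0.0794, with a median of -0.29. When each library was left out the median ranged from -0.403 to -0.145, without vehicle 2 and without vehicle 4, and the adjusted p from 0.00569 to 0.289, under the threshold in 3 of 12 cases. Among lists of endocrine cells, the preset camera adjusted p was 0.804 for somatotroph genes (led by Sstr3 and Sstr2), 0.236 for lactotroph genes (Prl and Akr1c14), 0.454 for corticotroph and melanotroph genes (with Tbx19 among the members of smallest p) and 0.614 for stem and progenitor genes (Prrx1 and Aldh1a2). For stress and growth, it was 0.278 for stress-axis signalling (Fkbp5 and Tbx19), 0.721 for glucocorticoid-responsive genes (Fkbp5 and Hif3a) and 0.375 for the growth hormone and insulin-like growth factor axis (Stat5b and Stat5a). Fkbp5 had a log2 fold change of 0.16 (SE 0.05, limma adjusted p 0.976). For regulation of RNA and chromatin, it was 0.239 for microRNA processing (Lin28b and Tarbp2), 0.353 for imprinted genes (Asb4 and Usp29) and 0.413 for DNA methylation and chromatin silencing (Eed and Dnmt1). It was 0.232 for proliferation (Mki67 and Plk1), 0.534 for immediate early genes (Egr3 and Klf6), 0.454 for the circadian clock (Bhlhe41 and Nr1d1), 0.232 for secretory granules (Pcsk1n and Syt1), 0.454 for the unfolded protein response (Edem1 and Sdf2l1), 0.614 for mitochondrially encoded genes (mt-Nd6 and mt-Nd5) and 0.529 for the interferon response (Ifit2 and Oas1a). Among lists of other cells, it was 0.288 for endothelium (Esm1 and Plvap), 0.804 for pericytes and smooth muscle (Acta2 and Myh11), 0.35 for fibroblasts (Loxl1 and Pdgfra), 0.158 for macrophages and other immune cells (H2-Ab1 and Cd74), 0.437 for erythrocytes (Slc4a1 and Hbb-bs) and 0.336 for neurons and glia (Slc17a6 and Pdgfra). Adjusted over the list alone, 1 gene passed in each of 2 lists: Asb4 among the imprinted genes (limma adjusted p 0.0381) and Slc17a6 among the neuron and glia genes (limma adjusted p 0.0378). Both were lower in all 6 mimic libraries than the vehicle mean, at -0.36 and -0.36, and over all genes tested neither passed.

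The main axes of variation did not separate the groups. The first principal component of the 1000 most variable genes held 25.3% of the variance, with scores of 7.95 ± 4.02 in mimic and -7.95 ± 22.6 in vehicle glands (SD, n = 6 each, exact two-sided permutation p 0.152, adjusted p 0.455 over 3 tests). The second held 14.4% (exact two-sided permutation p 0.926). The Y-linked gene Ddx3y was present at 3707 to 5137 normalised counts in all 12 libraries, as the male label requires, and Xist was not among the genes in the table.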

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

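In this part, the tests of a length trend and of vehicle 3 and vehicle 4 were chosen after the result was seen. A library was singled out where its gap to the nearest other library of its group took up an unusually large part of the group's range. This held for 15 of the 208 group values tested, where chance gives about 10.4. In vehicle 3, H3c3 was at 164.8 normalised counts (48.1 to 73.5 in the other vehicle libraries), Ifit2 at 300.5 (172.5 to 198.3), Mtres1 at 388.7 (302.5 to 332) and Gata2 low at 794.9 (1091 to 1244). In vehicle 4, Atp5f1d was at 2450 (1706 to 1908) and the row without a gene name was low at 0.0359% of reads (0.0456% to 0.0511%). In vehicle 1, Slc8a3 was at 301.5 (214.2 to 238.6) and Hmga2 at 168.3 (133 to 141.1). In vehicle 5, Acvr1c was low at 748.9 (1632 to 2499). In mimic library 1, Akr1c14 was at 86.4 (20.8 to 32.2), Lhb low at 8019 (9263 to 10043) and Usp29 low at 2361 (2882 to 3104). In mimic library 2, H3c3 was at 96.6 (42.5 to 53.9). In mimic library 4, Taf6l was at 523.8 (362.5 to 414.5) and Tshb low at 3816 (5863 to 6697).

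The ribosomal protein genes of vehicle 3 and vehicle 4 lay 0.30 and 0.27 (log2) above the mean of all libraries, and the other 10 libraries lay between -0.21 and 0.08. Without both libraries the median log2 fold change of the ribosomal list was 0.006, and the list did not pass (preset camera adjusted p 0.706). They were picked as the vehicle libraries with the highest level, and leaving them out pulls the difference toward 0 by itself, so whether the call comes from them cannot be told apart from a shift of the mimic group. Without either alone the list passed, at medians of -0.0596 and -0.0633. The oxidative phosphorylation list (0.21 and 0.24) and the thyrotroph list (0.18 and 0.24) were also above the mean of all libraries in vehicle 3 and vehicle 4. So were the histone list (0.60 and 0.19) and the gonadotroph list (0.03 and 0.46). Mimic library 2 also had a histone level of 0.19. The posterior lobe markers lay at 1.38 in vehicle 3 and -0.68 in vehicle 4. Without both libraries 7 lists passed. Whether a trend with transcript length lies behind the call cannot be told. With a curve on length removed from each library, the ribosomal median was -0.12 against -0.11 before, but this correction moved 99% of genes by 0.033 or less and no gene by more than 0.077, so it tested little. Of the other genes, 381 of similar length and at least the lowest ribosomal level had a median log2 fold change of -0.043. Only 1 of the 20 histone genes had a length under its symbol, so that list could not be corrected. Chance cannot be excluded for the number of lists: 65 of 100 splits of the 12 samples, the real one included, gave at least the real 6. The other splits gave a median of 8 lists, above the real 6, and the highest gave 17. The preset adjusted p values therefore do not by themselves point to a difference between the groups.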

How the results depend on the processing

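The transcript length correction and the use of the posterior lobe markers as a covariate for lists were chosen after seeing the data. The count of 0 genes (0 higher, 0 lower) held under 23 of 24 alternatives, with 606 to 1190 genes at an unadjusted p under 0.05. The exception was DESeq2, with 10 genes, 2 higher and 8 lower, on recovered reads. The cause was not tested. In simulation 19.7% of its calls were false, but the simulated counts held genes that had been made to change. That share therefore does not carry over to these 10 genes. Other splits of the 12 samples gave a median of 3 genes with DESeq2, and 6 of 40 splits gave at least 10. With limma, leaving out each library gave 0 to 0 genes.

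The 6 lists became 0 with the correlation between list members estimated from the data, a setting that also changes camera's degrees of freedom. They became 0 with fry, which also tests another hypothesis. The cause was not tested in either case. Leaving out each library gave 5 to 9 lists. The histone list was lost without vehicle 3, the posterior lobe list without vehicle 1 or vehicle 6, the thyrotroph list without mimic library 4, and the oxidative phosphorylation list without vehicle 3, vehicle 4 or mimic library 3. The hormone list passed without vehicle 2, vehicle 5 or mimic library 5. Lists outside these passed too: immune genes without vehicle 1 or vehicle 2, microRNA processing without vehicle 2, proliferation, fibroblast and neuron-glia genes without vehicle 3, immediate early genes without vehicle 4, and lactotroph genes without vehicle 5. With the posterior lobe markers as a covariate, 5 lists passed (the thyrotroph and posterior lobe lists were lost and immune genes gained), the median of the posterior lobe list became -0.0511 by construction, and that of the let-7 target list 0.0097.

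Apart from the posterior lobe list, reversals were of values that had not passed. The hormone share difference ranged from -0.453 to 0.5344 percentage points when each library was left out (exact permutation p 0.463 to 0.978), and vehicle 4 gave the highest. The let-7 target list ranged from -0.011 to 0.019, Gh from -0.0503 to 0.0987, Igf1r from -0.0769 to 0.0376, Insr from -0.027 to 0.0471, Irs2 from -0.1167 to 0.0649 and Hbb-bs from -0.4289 to 0.0402. Gh was -4e-04 with edgeR and -0.0015 with DESeq2, and Irs2 was 0.0741 with library weights. The cause was not tested. Of 2372 comparisons of 99 named genes, 2344 kept direction and side of the threshold. The seed match difference (0.0094 to 0.0099 for stricter sites) and the first principal component over all kept genes (20.6) kept theirs.

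Replicate numbers did not pair the samples: the deviations of same-numbered libraries correlated between -0.15 and 0.09, and a library's best match was its own number in 2 of 12 cases. With the replicate number as a block, 0 genes passed, with 837 at an unadjusted p under 0.05, and 6 lists passed, so no call changed.

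Depth was not varied, so its part in the width of the intervals was not tested; changes well under 2-fold remain open.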

Other observations

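In this part, the tests on Pomc and on genes at 2 levels were chosen after the result was seen. With limma, the real split of the 12 samples called 0 genes, which all 100 of 100 splits (out of 462 possible) must equal or exceed, so this count tests nothing; the highest other split gave 6. Chance cannot be excluded for the counts that follow. At an unadjusted p under 0.05, 39 of 100 splits gave at least the real 879 genes, and the highest gave 3263, which points to a structure of the samples other than the groups. With DESeq2, 6 of 40 splits gave at least the real 10 genes, and the highest other split gave 109. For the let-7 sites, 70 of 100 splits gave as large a mean difference as the real 0.0043, and the highest was 0.0302.

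Pomc had a log2 fold change of 1.14 (SE 0.51), and the melanotroph genes Pax7, Oacyl and Pcsk2 had 1.23 (95% interval -0.12 to 2.57), 1.59 (0.23 to 2.96) and 0.77 (0.04 to 1.51). The limma adjusted p was 0.976 for each, and the list of corticotroph and melanotroph genes did not pass (preset camera adjusted p 0.454, median -0.052). These genes were not named by the rule, apart from Pomc, and were chosen after their values were seen. Vehicle 1, 4 and 6 had the lowest Pax7, at 145.2, 431 and 85.1 normalised counts, against 587.5 to 1924 in the other 9 libraries, and the lowest Pomc, at 45286, 93810 and 50197. A rise in corticotroph genes stays open: the receptor genes Crhr1 and Avpr1b had a mean log2 fold change of -0.14, with upper limits of 0.06 and 0.17, but Tbx19, which corticotrophs and melanotrophs share, had 0.49 (interval 0.09 to 0.89, unadjusted limma p 0.0192), and 0.16 with Pax7 as a covariate (-0.03 to 0.35). With Pax7 as a covariate, the Pomc log2 fold change was 0.19 (SE 0.21, interval -0.25 to 0.64). Oacyl kept 0.38 (interval 0.01 to 0.74), and with the posterior lobe markers as the covariate Pomc kept 0.57 (SE 0.26, unadjusted limma p 0.0467). A different share of intermediate lobe among the libraries may therefore account for part of the Pomc difference, and whether it accounts for all of it stays open. Whether that share was set at dissection or by the treatment cannot be read from these data, so a treatment effect on the lobe stays open as untested. Kit ranged from 0.8487 to 1.1087 in the leave-one-out fits, where its sign could not change because its groups did not overlap.

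Some genes stood at 2 separate levels, with a division of the libraries other than that into the groups. Of 60 such genes (a gap above 0.8 on the log2 scale and above 3 times the spread within levels, mean above 50), 17 followed the posterior lobe markers. Among these 17 were Scn7a, Col25a1 and Lhx2, which are themselves such markers, so that their agreement was partly built in. The other 43 showed 39 patterns of high and low libraries, with mirror images counted as different patterns. Of these 43, 0 separated all vehicle from all mimic libraries, and divisions that followed the groups in part were not counted. A gene with such a full separation would probably have passed limma, which called 0 genes, so this count adds little. Tlr7, called by DESeq2, was among the 43 and was high only in vehicle 1, 2 and 3. A pair of related genes showed the mirror image of each other: Spata31f1c was between 206 and 242 normalised counts in 6 libraries and between 0 and 14.7 in the others, where Spata31f1d was higher, at 293 to 350 against 96.7 to 130. For these 2 genes, reads shared between paralogs and divided differently by the quantification are a candidate explanation. For the other 41 no partner of the same family was found, and shared reads cannot be told apart from other causes because partners may be missing from the filtered table. For autosomal genes, a strain variant that differed between animals would go against the label, since F1 animals of 2 inbred strains carry the same autosomal alleles. The argument does not cover genes on the sex chromosomes, for which a strain variant stays open. The test on neighbouring genes could not decide by itself. In it, 0 of 9 pairs of such genes within 10 Mb shared their division of the libraries, which is too few pairs.

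The vehicle libraries appeared more variable than the mimic libraries, with 61.7% of genes having the larger variance in the vehicle group. Chance cannot be excluded for this: 26 of 100 splits, the real one included, gave as large a share, and the highest other split gave 71.7%.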
